A study of Mus musculus with 9 samples.

How the data were processed

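RNA sequencing libraries were made from mouse (C57BL6/J) central nervous system at embryonic day 9.5 (E9.5), embryonic day 14.5 (E14.5) and postnatal day 60 (P60), with 3 libraries per stage. Per the labels' protocols, E9.5 tissue was the head severed behind the 4th ventricle with surplus tissue outside the neuroectoderm taken off, E14.5 tissue was brain without meninges, and P60 tissue was taken after perfusion with saline. Libraries were made with an ultra-low-input kit that primes on poly(A) tails and amplifies full-length cDNA by PCR. The deposited table held raw read counts per gene. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and aligned with STAR 2.5.2b to the mm10 genome. The counting program, the gene annotation and the strand setting were not given in the sources used here, so genes that overlap on opposite strands may share reads in these counts.

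The table held 45706 gene identifiers, of which 45143 matched GENCODE M21 (GRCm38), the source of the symbols, coordinates and transcript lengths used. No read was counted for 16156 identifiers. In order of replicate number, library totals were 30585255, 30481975 and 31266724 counts at E9.5, 32522414, 33685108 and 32194254 at E14.5, and 31288920, 35356654 and 35619093 at P60. All columns of the table were used. Intervals of count ratios and floors cover only the counting error of the summed reads of a stage, not the spread between libraries. PCR copies were not marked by molecular identifiers, so the counting error itself may be larger.

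Each gene was tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by stage, robust quasi-likelihood fit) in a single fit of the 9 libraries with stage as the only factor. The filter kept 17971 genes. The 3 contrasts were E14.5 against E9.5, P60 against E14.5 and P60 against E9.5, each two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Counts of genes changed at least 2-fold were added, and an F test covered the 3 stages together. Genes were placed in temporal classes by their calls of at least 2-fold in the 2 consecutive steps. The common dispersion was 0.0394, a biological coefficient of variation of 19.9%. The spread between libraries, not the depth, therefore limits the precision of abundant genes.

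Gene lists (41) and gene pairs (20), the tests and the rule for naming genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (counts scaled to the TMM-adjusted library total, prior count 2). The inter-gene correlation was preset at 0.01, with adjustment over lists and contrasts. The test was repeated with the correlation estimated per list. Members were also counted as higher, lower or not called, with the adjustment over all genes and adjusted over the list alone. Pair ratios were the log2 of (CPM + 1) of the first gene over the second per library, tested by an exact permutation test of the F statistic over all 1680 assignments of the 9 libraries to 3 groups of 3. The smallest p-value this test can give is 0.0036.

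Named genes were chosen by rule. For each consecutive step these were the 8 largest rises and the 8 largest falls with a mean of at least 20 CPM in the higher stage and no overlap between libraries, leaving out predicted and clone-named genes. For P60 against E9.5 the rule took 4 and 4. From each list and step it took up to 3 called members in the majority direction and 1 in the other, and it took both genes of each pair and 8 genes each from the rise-fall and fall-rise classes. Some genes that the rule named, and the values of 1 pair, are not reported here. In 3 against 3 libraries, chance separates the groups without overlap for 10% of genes. Fold changes are fitted log2 values ± SE. The SE is approximate, taken as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. Where a stage had no reads for a gene, a lower bound is given that sets 3 counts in place of 0, and where it had 1 to 3 reads the ratio of counts is given with a 95% interval.

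The scripts were tested on simulated counts drawn for the 17971 genes, with 200 genes changed per contrast. For E14.5 against E9.5, where 17569 genes entered the fit, 46% of 2-fold and 85% of 4-fold changes were recovered. For P60 against E14.5 (17553 genes) the shares were 53% and 91%, and for P60 against E9.5 (17540 genes) 55% and 88%. Of the calls, 5.8%, 4.6% and 7.7% were unchanged genes. In the data 64.6 to 82.6% of genes were called per contrast, far more than the 200 changed in the simulation. These shares therefore need not hold for the data, and the simulation does not test the scaling where most genes change. In 10 simulations with no change between stages, no gene was called in both steps. At most 1 gene was called in a single step there, so they cannot show how many genes the shared E14.5 libraries add to a class.

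Alternatives tried were other scalings (median of ratios, upper quartile, library totals, TMM without globin and mitochondrial genes), DESeq2 1.42.0, limma-voom, a test against 2-fold, a threshold of 0.01, no filter and a stricter filter, equal depth, only the 6 libraries compared, the replicate number as a block, other minimum sizes and pseudocounts, and leaving out each library. Removal of a transcript length and GC trend was added after the data were seen.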

Results

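Gene expression was measured in mouse central nervous system tissue at E9.5, when the neural tube is closing, at E14.5, within cortical neurogenesis, and in the adult at P60, with 3 libraries per stage and 30481975 to 35619093 counts per library. The comparisons ask which genes and which cell and pathway genes differed between consecutive stages and over the whole interval. Across genes, the correlation of log2 CPM was 0.98 to 0.995 between libraries of a stage and 0.61 to 0.857 between stages. The first principal component held 75.6% of the variance and the second 19.5%. Expression values are mean CPM ± SD with n = 3 libraries per stage, and p-values of genes are adjusted over all genes tested, those of lists over lists and contrasts, and those of pairs over the 20 pairs. The labels do not say that the replicates are separate animals, so p-values measure only the spread between these samples. Of 17971 genes tested, 16441 differed across the 3 stages. Of 50 splits of the 9 libraries, only the real one gave that many, and the next gave 8700 and kept 1 stage whole. The 46 splits that kept no stage whole gave 0. Such splits mix stages within groups, which widens the spread there, so few calls could come from them. The comparison with these splits therefore lends no support.

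From E9.5 to E14.5 the early embryonic genes fell and neuronal genes rose. Lin28a, an RNA-binding protein that blocks let-7 maturation, fell from 614 ± 52.5 to 0.719 ± 0.309 CPM, and Trim71, another let-7 pathway gene, fell from 200 ± 11.3 to 0.861 ± 0.393 CPM. Tbr1, a transcription factor of deep-layer cortical neurons, rose from 0.286 ± 0.13 to 168 ± 26.8 CPM. Bcl11a and Bcl11b, zinc finger factors of postmitotic neurons, rose from 0.818 ± 0.196 to 230 ± 9.12 and from 0.935 ± 0.437 to 259 ± 16.9 CPM. All 30 cell cycle genes fell. In all, 11613 genes changed, 6104 higher and 5509 lower, and 7823 of them changed at least 2-fold (4572 higher, 3251 lower). The balance of all changed genes turned with the scaling, to 5781 higher and 5971 lower under median-of-ratios scaling.

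Lin28a (chromosome 4, 134003330 to 134018841, GRCm38) had a log2 fold change of -9.74 ± 0.34 (adjusted p = 1.1e-08). Prtg, a receptor of the early neural tube, fell from 628 ± 43.4 to 2.88 ± 0.655 CPM (-7.76 ± 0.25, adjusted p = 8.3e-09). Hmga2, a chromatin protein of young progenitors, fell by 5.62 on the log2 scale (adjusted p = 1.4e-08), and Cldn6, a tight junction protein of embryonic epithelia, fell by 7.69 (adjusted p = 2.6e-08). All 12 early embryonic and heterochronic genes were lower. Within the cell cycle list the largest falls were in Ccne1, the cyclin of S phase entry (-3.48 ± 0.18, adjusted p = 5.7e-08), Cdc6, a replication licensing factor (-2.87 ± 0.15, adjusted p = 5.3e-08), and Mcm5, a subunit of the replicative helicase (-2.55 ± 0.14, adjusted p = 7.5e-08). The camera test called the cell cycle list lower at an adjusted p of 2e-11 with the preset correlation. With an estimated correlation the adjusted p was 0.079.

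All 20 immature neuron genes, all 25 mature neuron and synapse genes and all 16 inhibitory neuron and neuropeptide genes rose. Tbr1 (chromosome 2, 61802930 to 61814114) rose by 9.18 ± 0.50 on the log2 scale (adjusted p = 8.3e-08). Dcx, a microtubule protein of migrating neurons, rose from 17.6 ± 4.58 to 1270 ± 343 CPM (6.17 ± 0.39, adjusted p = 2.4e-07). Among synaptic genes, the AMPA receptor subunits Gria1 and Gria2 rose 124-fold and 247-fold (adjusted p = 7.9e-09 and 2.5e-08), and Slc17a6, a vesicular glutamate transporter, rose 145-fold (adjusted p = 1.4e-08). Of 18 neurogenic transcription factors 14 rose and 2 fell, and Neurog1, a proneural factor, was the larger of the falls (-1.24 ± 0.24, adjusted p = 0.001). Neurod2, a factor of cortical projection neurons, had a fitted rise of 10.98, which became 13.18 without the first E9.5 library. Of 16 voltage-gated ion channels 13 rose and 0 fell, led by the sodium channel Scn3a (6.26 ± 0.39, adjusted p = 2.1e-07).

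Glial and immune genes rose in part. Of 17 astrocyte genes 11 rose and 1, the gap junction gene Gja1, fell (-1.82 ± 0.22, adjusted p = 3.3e-05). Aldh1l1, a folate enzyme of astrocytes, rose from 1.2 ± 0.477 to 47.7 ± 4.53 CPM. Of 18 radial glia genes 7 rose and 3 fell, and the matrix protein Tnc rose most (5.48 ± 0.30, adjusted p = 8.6e-08). Oligodendrocyte precursor genes numbered 6 higher and 3 lower of 10, with Olig1, a lineage transcription factor, up 32-fold (adjusted p = 5.6e-08) and Sox10 lower (-2.73 ± 0.34, adjusted p = 3.4e-05). Myelin genes numbered 9 higher and 3 lower of 18. Microglial genes rose in 16 of 17 cases. C1qa, a complement component, rose from 0.142 ± 0.125 to 11.1 ± 4.11 CPM (adjusted p = 1e-06), and Siglech, a microglial lectin without reads at E9.5, rose at least 38.5-fold. Tmem119 was the exception and fell from 19 ± 0.462 to 3.67 ± 1.04 CPM (adjusted p = 2.2e-06). Border macrophage genes numbered 6 higher and 0 lower of 7. Antigen presentation and complement genes numbered 5 higher and 1 lower of 10, immediate early genes 4 and 1 of 10, and circadian output genes 4 and 2 of 10.

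Most genes of surface ectoderm, mesenchyme and neural crest fell. All 11 surface ectoderm genes were lower, including Grhl2, an epithelial transcription factor (-6.08 ± 0.27, adjusted p = 2.5e-08), and Esrp1, an epithelial splicing factor (-5.94 ± 0.32, adjusted p = 7.8e-08). Mesenchyme genes numbered 11 lower and 2 higher of 15, with Twist1, a mesenchymal factor, down 21.8-fold (adjusted p = 4.5e-08) and the collagen-binding proteoglycan Dcn up 38.5-fold (adjusted p = 1.3e-07). Neural crest genes numbered 9 lower and 1 higher of 11, among them Snai1 (-3.51 ± 0.23, adjusted p = 2.9e-07) and the retinoid-binding protein Crabp1 (-4.80 ± 0.31, adjusted p = 2.8e-07). Of 7 tested muscle genes 5 were lower. The size of these falls rested on the first E9.5 library, where Actc1, a cardiac actin, had 130 CPM against 2.95 and 2.90 CPM in the others. Without that library Actc1 kept its call with -2.93 in place of -6.90, as did Myl7, an atrial myosin light chain (-3.90 in place of -7.59). Tnnt2, cardiac troponin T, lost its call (-0.63), and lost it also without any single E14.5 library. Only 4 of 20 listed Hox genes had enough reads to be tested, and 3 fell, of which Hoxb2 lost its call when the first E9.5 or last E14.5 library was left out. Eye field and pigment genes split into 2 higher and 2 lower of 6, and 1 of 2 tested pituitary genes, Pomc, rose (adjusted p = 0.035, lost when any of 3 single libraries was left out). The tissue taken differed between these stages, so dissection and age cannot be told apart for such genes.

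Patterning and signalling genes fell more often than they rose. Regional patterning genes numbered 11 lower and 6 higher of 22, with Fgf8, the midbrain-hindbrain organiser signal, down 27.3-fold (adjusted p = 3.2e-07) and Emx1, a dorsal telencephalic factor, up 14.9-fold (adjusted p = 1.9e-07). Hedgehog and Wnt genes numbered 13 lower and 1 higher of 18, with Gli1, a Hedgehog target (-3.10 ± 0.26, adjusted p = 2.1e-06), and Fzd7, a Wnt receptor (-2.55 ± 0.16, adjusted p = 2.5e-07), among the falls. Wnt7b, a ligand for brain vessels, was the gene that rose (1.38 ± 0.16, adjusted p = 2.1e-05). Retinoic acid genes numbered 6 lower and 3 higher of 12, and imprinted genes 8 lower and 5 higher of 14. The imprinted growth gene Mest fell 10.4-fold (adjusted p = 5.6e-07), while Ndn, a neuronal survival gene, rose 6.74-fold (adjusted p = 1.2e-07). Brain matrix genes numbered 6 higher and 3 lower of 9. The proteoglycan gene Ncan rose from 7.77 ± 0.941 to 561 ± 29.4 CPM (adjusted p = 3.8e-08) and the link protein gene Hapln1 fell from 78 ± 16.4 to 1.04 ± 0.615 CPM (adjusted p = 1.3e-07).

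In metabolism, glycolytic genes numbered 13 lower and 6 higher of 19. Ldha, lactate dehydrogenase A, fell from 2530 ± 218 to 272 ± 50 CPM (-3.22 ± 0.18, adjusted p = 1.2e-07), the glucose transporter Slc2a3 fell 11.3-fold (adjusted p = 5.4e-08), and Aldoc, the aldolase of astrocytes, rose 33.8-fold (adjusted p = 4.5e-08). Of 82 cytosolic ribosomal protein genes 55 were lower and 0 higher, with Rps2 down 3.35-fold (adjusted p = 0.00013). The E14.5 libraries had 4.01, 2.35 and 2.33% of counts in such genes. The median of the list, -0.90, ranged from -1.27 without the first of them to -0.75 when others were left out. Counts of ribosomal protein genes may include reads of their pseudogenes. Of 79 nuclear-encoded oxidative phosphorylation genes 4 were lower and 0 higher, and 0 of 7 tested mitochondrially encoded genes changed. Cholesterol synthesis genes numbered 4 higher and 4 lower of 19. BAF (chromatin remodelling) subunits numbered 10 higher and 7 lower of 26, with the neuronal subunit Actl6b up 304-fold (adjusted p = 7.9e-09). Polycomb and DNA methylation genes numbered 8 lower and 3 higher of 18, with Uhrf1, a maintenance methylation factor, down 6.66-fold (adjusted p = 8.5e-07).

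Vessel and blood genes were mixed. Of 12 endothelial genes 1 rose and 2 fell. The rise was in Cldn5, the tight junction protein of brain vessels (1.63 ± 0.22, adjusted p = 8e-05), and the larger fall was in Plvap, a marker of leaky vessels (-2.76 ± 0.17, adjusted p = 2e-07). Barrier transport genes numbered 6 higher and 4 lower of 11, with the thyroid hormone transporter Slco1c1 up 25-fold (adjusted p = 1.1e-07) and the lactate transporter Slc16a1 down 7.83-fold (adjusted p = 2.4e-08). Mural cell genes numbered 6 higher and 2 lower of 10, led by Rgs5 among those with more than 3 reads at E9.5 (5.91 ± 0.43, adjusted p = 6.1e-07). Erythroid genes numbered 8 lower and 4 higher of 12, and embryonic globin Hbb-bh1 (chromosome 7, 103841637 to 103843164) fell from 1710 ± 275 to 1.91 ± 0.68 CPM (-9.81 ± 0.36, adjusted p = 1.1e-08). Choroid plexus genes numbered 7 higher and 0 lower of 9, and ependymal cilia genes 5 higher and 0 lower of 9. Camera called 9 lists higher and 9 lower, none with an estimated correlation. Among the 10 ways to split these 6 libraries into 3 and 3, 4 gave at least as many called lists, so statements here rest on member counts. The same splits gave 0 changed genes apart from the real one, but the others mix stages within groups, and 10 splits cannot reach 0.05. Member counts are not tests of the lists. Over all 17971 genes 64.6% were called in this step, 6104 higher and 5509 lower. A list near that share, such as BAF subunits with 10 higher and 7 lower of 26, is not set apart from other genes. For 36 of 41 lists the number of members called was the same when adjusted over the list alone, and the totals were 484 against 483 over all genes. The 4 oxidative phosphorylation falls were not among those called over the list alone. For eye field genes the median (0.46) and mean (0.77) were above 0 and the test pointed down.

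**Figure D1:**
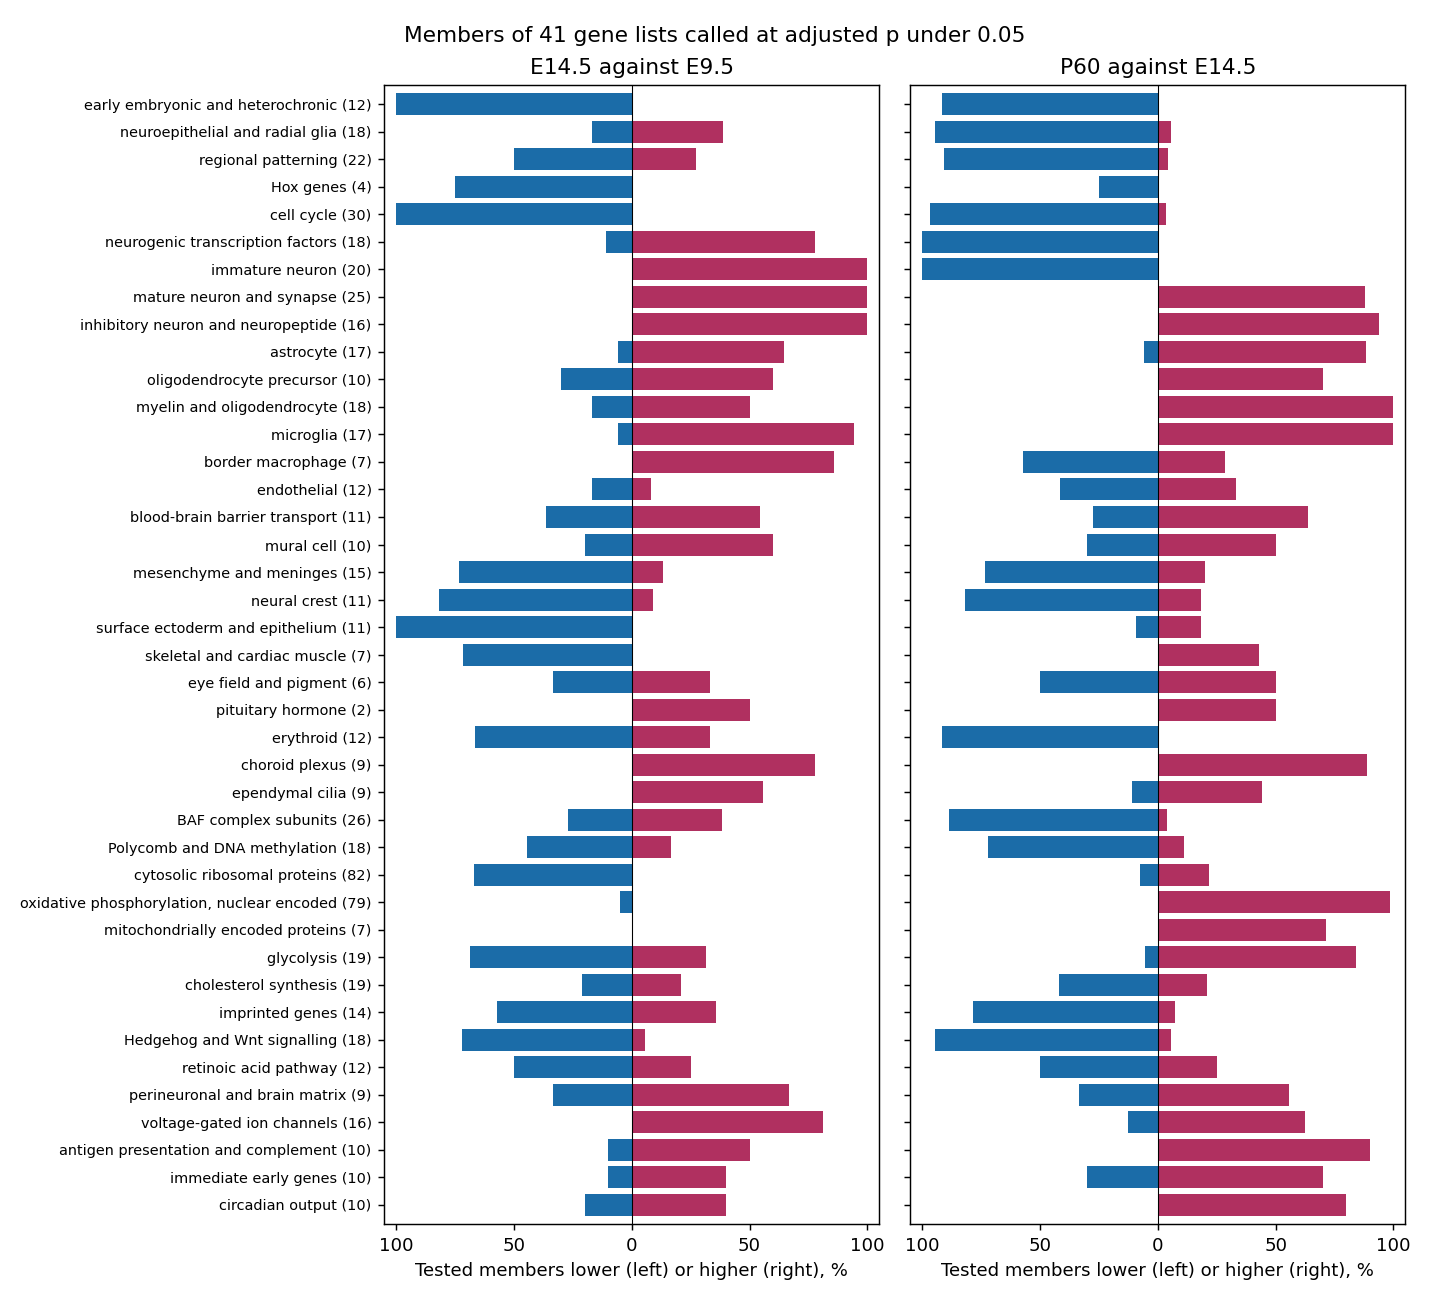
Share of the tested members of each of 41 gene lists (number tested in parentheses) that were lower (left bars) or higher (right bars) at an adjusted p under 0.05, in percent, for E14.5 against E9.5 and P60 against E14.5. All 20 immature neuron genes were higher in the first step and all 20 lower in the second.

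From E14.5 to P60, genes of newborn neurons and progenitors fell and those of myelin, mature neurons and glia rose. Sox11 and Sox4, transcription factors of newborn neurons, fell from 1290 ± 135 to 4.64 ± 0.777 and from 382 ± 25.9 to 5.45 ± 1.06 CPM. Dcx fell from 1270 ± 343 to 5.72 ± 2.71 CPM. Mobp, a structural myelin protein, rose from 0.974 ± 0.926 to 2390 ± 324 CPM, and Agt, the angiotensinogen gene of astrocytes, rose from 0.174 ± 0.0268 to 121 ± 16.3 CPM. All 18 myelin genes rose. In all, 13681 genes changed, 6601 higher and 7080 lower, and 10205 of them changed at least 2-fold (4865 higher, 5340 lower). The balance of all changed genes turned here too, to 7248 higher and 6496 lower under upper quartile scaling, while library totals gave 6089 and 7585, so no majority direction is given.

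All 20 immature neuron genes and all 18 neurogenic transcription factors fell. Sox11 (chromosome 12, 27334264 to 27342574) fell by 8.12 ± 0.21 on the log2 scale (adjusted p = 2.9e-09). Dcx (chromosome X, 143855842 to 143933311) fell by 7.79 ± 0.42 (adjusted p = 6.7e-08), and Neurog2, a proneural factor, fell by 7.40 ± 0.22 (adjusted p = 3.5e-09). Of 18 radial glia genes 17 fell and 1, the glutamate transporter Slc1a3 that astrocytes keep, rose (2.59 ± 0.21, adjusted p = 1.2e-06). Nes, an intermediate filament of progenitors, fell from 507 ± 115 to 7.06 ± 1.75 CPM (adjusted p = 1.6e-08). Of 30 cell cycle genes 29 fell, with Top2a, a topoisomerase of dividing cells, down 223-fold (adjusted p = 3.5e-09) and the mitotic checkpoint kinase Bub1 down 160-fold (adjusted p = 3.4e-09). Ccne1 rose from 11.9 ± 2.61 to 32.2 ± 2.67 CPM (adjusted p = 1.7e-05). Early embryonic genes fell in 11 of 12 cases. Regional patterning genes numbered 20 lower and 1 higher of 22 (Egr2, whose call was lost without any of 3 single libraries), with Barhl1 down 58-fold (adjusted p = 8.2e-09) and Nkx2-1 down 39.5-fold (adjusted p = 3.4e-08). Hedgehog and Wnt genes numbered 17 lower and 1 higher of 18, and Gli3, a Hedgehog repressor, fell 27.5-fold (adjusted p = 5.7e-08). Hhip, a Hedgehog-binding inhibitor, was the gene that rose (1.25 ± 0.27, adjusted p = 0.0014).

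Mobp (chromosome 9, 120149707 to 120181484) had the largest rise by the rule, 11.24 ± 0.60 on the log2 scale (adjusted p = 6.2e-08), and 12.39 without the second E14.5 library. Agt (chromosome 8, 124556534 to 124569706) rose by 9.41 ± 0.31 (adjusted p = 4.6e-09), Myoc, a secreted glial protein, by 10.17 ± 0.32 (adjusted p = 3.9e-09), and Gpr37l1, an astrocyte receptor, by 9.46 ± 0.35 (adjusted p = 6.6e-09). Camera called the myelin list higher at an adjusted p of 1.3e-09. With an estimated correlation the adjusted p was 0.079. Oligodendrocyte precursor genes numbered 7 higher and 0 lower of 10, with Bcas1, a gene of newly formed oligodendrocytes, up 67.3-fold (adjusted p = 3.4e-09). Astrocyte genes numbered 15 higher and 1 lower of 17, and the progenitor factor Sox9 was the one that fell (-1.89 ± 0.16, adjusted p = 1.7e-06). Microglial genes rose in 17 of 17 cases, among them Siglech (4.10 ± 0.18, adjusted p = 1.2e-07) and the protease gene Ctss (3.93 ± 0.21, adjusted p = 5.7e-08). Border macrophage genes instead numbered 4 lower and 2 higher of 7, with the mannose receptor Mrc1 (-2.17 ± 0.21, adjusted p = 4.3e-06) and F13a1 (-2.05 ± 0.22, adjusted p = 9.1e-06) among the falls. Antigen presentation and complement genes rose in 9 of 10 cases, with the immunoproteasome subunit Psmb9 up 16.4-fold (adjusted p = 4.4e-06).

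Mature neuron genes numbered 22 higher and 0 lower of 25. Thy1, a surface protein of projection neurons, rose from 4.74 ± 1.77 to 918 ± 18.5 CPM (7.60 ± 0.42, adjusted p = 6.8e-08). Nrgn, a postsynaptic calmodulin-binding protein, rose 137-fold (adjusted p = 5.1e-08). Inhibitory neuron genes numbered 15 higher and 0 lower of 16, including the interneuron markers Vip (7.51 ± 0.30, adjusted p = 8.7e-09) and Pvalb (7.87 ± 0.44, adjusted p = 8.1e-08). Voltage-gated channels numbered 10 higher and 2 lower of 16. The sodium channel subunit Scn4b rose 94.8-fold (adjusted p = 4.2e-08), while the embryonic channel Scn3a fell 6.53-fold (adjusted p = 1.8e-05). Brain matrix genes numbered 5 higher and 3 lower of 9, with the link protein Hapln4 up 121-fold (adjusted p = 3.7e-08) and Tnc down 19-fold (adjusted p = 2.3e-07). Immediate early genes numbered 7 higher and 3 lower of 10, among them Egr1 (4.30 ± 0.31, adjusted p = 4.7e-07) and the phosphatase gene Dusp1, which fell (-0.82 ± 0.13, adjusted p = 2e-04). Circadian output genes numbered 8 higher and 0 lower of 10, with Dbp up 15.6-fold (adjusted p = 2.9e-08). The time of day of collection is not given.

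Energy genes rose. Of 79 nuclear-encoded oxidative phosphorylation genes 78 were higher and 0 lower, with a median log2 fold change of 1.77, and 1.20 with the length trend given next removed. Cox8b, a muscle isoform without reads at E14.5, rose at least 217-fold and lies above the median at that bound. Of 7 tested mitochondrially encoded genes 5 rose, with mt-Nd6, a complex I subunit, up 2.82-fold (adjusted p = 5.9e-05). Of the 5, mt-Nd1 and mt-Nd5 lost their calls without the second P60 library, and 6 of 13 such genes had too few counted reads to be tested. Glycolytic genes numbered 16 higher and 1 lower of 19. Eno2, the neuronal enolase, rose from 48.6 ± 6 to 1370 ± 19.3 CPM (4.82 ± 0.16, adjusted p = 4.6e-09), and Hk2, the hexokinase of proliferating cells, fell 9.42-fold (adjusted p = 5.7e-07). Ribosomal protein genes numbered 18 higher and 6 lower of 82, with a median of 0.30 that became -0.28 with the trend removed. Their share of counts was 3.73, 2.24 and 4.04% in the P60 libraries, and the median was 0.11 to 0.63 when single libraries were left out. Only 7 were called when adjusted over the list alone. Cholesterol synthesis genes numbered 4 higher and 8 lower of 19, with Lss, lanosterol synthase, down 3.51-fold (adjusted p = 1.1e-05) and Msmo1, a later enzyme, up 2.51-fold (adjusted p = 4.3e-05). Median change fell with transcript length in this step. It was 0.57 for transcripts under 1 kb and -1.32 for those over 8 kb, against -0.12 and 0.25 in the earlier step.

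**Figure D2:**
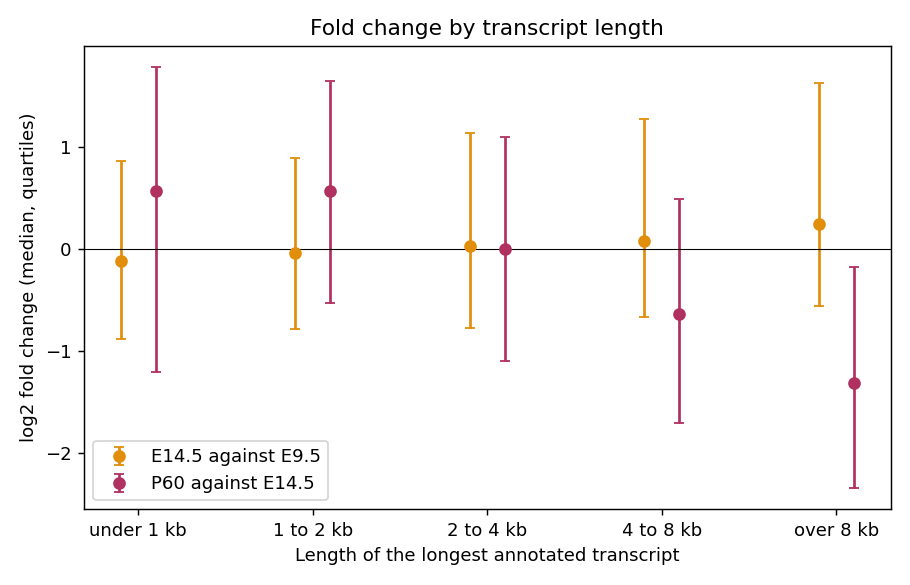
Log2 fold change by transcript length, as medians (points) with quartiles (bars) of the tested genes, for E14.5 against E9.5 and P60 against E14.5. Length is that of the longest protein-coding transcript of a gene, or of the longest of any type where it has none. From E14.5 to P60 the medians go from 0.57 under 1 kb to -1.32 over 8 kb.

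Chromatin genes fell. BAF subunits numbered 23 lower and 1 higher of 26, with Arid1a, a DNA-binding subunit, down 12.2-fold (adjusted p = 1.2e-06) and Bcl7b up 2.31-fold (adjusted p = 0.00011). The median of this list was -1.65, and -1.24 with the length trend removed. Polycomb and DNA methylation genes numbered 13 lower and 2 higher of 18. Ezh2, the Polycomb methyltransferase of dividing cells (chromosome 6, 47530139 to 47595341), fell from 167 ± 26.9 to 3.97 ± 0.415 CPM (-5.39 ± 0.18, adjusted p = 4.6e-09), while Cbx7, a Polycomb reader, rose 6.16-fold (adjusted p = 1.6e-07). Imprinted genes numbered 11 lower and 1 higher of 14. The growth-restraining transcript H19 fell from 262 ± 21.9 to 0.247 ± 0.14 CPM (-10.04 ± 0.36, adjusted p = 5.7e-09), and Snrpn, a neuronal splicing component, rose 2.76-fold (adjusted p = 2.3e-05).

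Erythroid genes fell in 11 of 12 cases, and Hbb-y, an embryonic globin, fell from 202 ± 71.2 to 0.167 ± 0.086 CPM (adjusted p = 1.4e-08). The P60 animals were perfused, so blood content differs by procedure. Endothelial genes numbered 4 higher and 5 lower of 12, with the VEGF receptor Kdr down 6.04-fold (adjusted p = 4.9e-07). Barrier transport genes numbered 7 higher and 3 lower of 11, with the organic anion transporter Slco1a4 up 19.8-fold (adjusted p = 6.9e-09) and the reelin receptor Lrp8 down 7.35-fold (adjusted p = 2.2e-06). Mural genes numbered 5 higher and 3 lower of 10. Mesenchyme genes numbered 11 lower and 3 higher of 15, with the collagen gene Col3a1 down 64.8-fold (adjusted p = 3e-08), and neural crest genes 9 lower and 2 higher of 11. Choroid plexus genes numbered 8 higher and 0 lower of 9, with Enpp2, autotaxin, up 23-fold (adjusted p = 9.4e-08). Ependymal cilia genes numbered 4 higher and 1 lower of 9, and the lower one, Foxj1 (-0.43), lost its call without any of 4 single libraries. Retinoic acid genes numbered 3 higher and 6 lower of 12, with the retinaldehyde dehydrogenase Aldh1a1 up 47.5-fold (adjusted p = 8.1e-08). Surface ectoderm genes numbered 2 higher and 1 lower of 11, muscle genes 3 higher and 0 lower of 7, eye field genes 3 higher and 3 lower of 6, and pituitary genes 1 higher of 2. The calls of the muscle rises were not stable. Acta1 and Tnnt2 lost them without any single library of these stages and Myl4 without any single E14.5 library. In those fits Tnnt2 still rose by 4.47 to 4.59 (4.53 in the main fit), Myl4 by 4.45 to 5.14 (4.71) and Acta1 by 1.95 to 2.37 (2.20). The single fit also takes in the E9.5 libraries, where Tnnt2 had 48.7, 0.431 and 0.479 CPM. The pituitary gene, Pomc, lost its call in 4 fits that left out a single library of these stages. Of the 4 tested Hox genes 1 fell.

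Camera called 12 lists higher and 13 lower in this step, none with an estimated correlation, and 5 of 10 splits gave at least as many. Over all genes tested 76.1% were called, 6601 higher and 7080 lower, so member counts near that share do not set a list apart. For 36 of 41 lists the number of members called was the same when adjusted over the list alone, and the totals were 553 against 570 over all genes. The 3 muscle rises were not called over the list alone. For eye field genes the median (-0.68) and mean (-0.62) were below 0 and the test pointed up.

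Over the whole interval from E9.5 to P60 some genes went from no reads to abundance. Hcrt, the orexin precursor of hypothalamic neurons, had no reads at E9.5 and 62.3 ± 29.7 CPM at P60, at least 1940-fold higher. Ctxn2, a small neuronal membrane protein, was at least 1120-fold higher. Ptgds, the prostaglandin D synthase of meninges and oligodendrocytes, rose from 0.0765 ± 0.069 to 1550 ± 226 CPM (14.23 ± 0.49, adjusted p = 1.1e-09), a fitted change that became 14.84 without the first E9.5 library. Lin28a had 1 read in all P60 libraries, a ratio of 60000 (95% interval 10800 to 2370000), and Igf2bp1, a let-7 target that binds RNA, also had 1 read, a ratio of 69700 (12500 to 2750000). Without the first P60 library the fitted changes went from -15.41 to -17.29 and from -15.63 to -17.50. In all, 14844 genes changed, 7546 higher and 7298 lower, and 12140 changed at least 2-fold (6302 higher, 5838 lower). With library totals 7406 genes were higher and 7415 lower.

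All 30 cell cycle genes and all 12 early embryonic genes were lower at P60 than at E9.5, and all 25 mature neuron, 16 inhibitory neuron and 17 microglial genes were higher. Immature neuron genes, which rose and then fell, ended with 11 higher and 8 lower of 20. Glycolytic genes ended with 9 higher and 8 lower of 19, and BAF subunits with 7 higher and 17 lower of 26. Over all genes tested 82.6% were called in this contrast, 7546 higher and 7298 lower. Camera called 14 lists higher and 13 lower, none with an estimated correlation, and 4 of 10 splits gave at least as many. Adjusted over the list alone, 39 of 41 lists had the same number of members called. For glycolysis (median -0.19, mean 0.85) and barrier transport (-0.48 and 1.79) the test pointed up against the median.

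Sorted by both steps, 1677 genes rose and rose again, 1295 fell and fell again, 1183 rose then fell and 652 fell then rose, each step being at least 2-fold. If the steps were independent, 1238, 966, 1359 and 880 genes would be placed in these classes. The E14.5 libraries enter both steps, so shared chance values can add to the last pair of classes, and the 3 libraries of a stage are too few to divide between the steps. Of 50 splits of the 9 libraries, 1 gave as many genes in each of the first pair of classes (the real one) and 2 in each of the last pair, the other being a split that kept 1 stage whole. Splits that mix stages within groups could give few calls, so these counts lend the classes no support. Among the genes the rule named in the rise-fall class, Trim67, a neuronal ubiquitin ligase, went from 0.704 ± 0.261 to 271 ± 25.3 and then 4.77 ± 0.207 CPM. Sox14, a factor of thalamic and midbrain interneurons, went from 0.251 ± 0.0618 to 21.4 ± 1.6 and 0.508 ± 0.169 CPM, and the hypothalamic factor Otp from 0.304 ± 0.173 to 25 ± 4.11 and 0.801 ± 0.175 CPM. Lhx1, a factor of several neuron types, and the adult globin Hbb-bt were also in this class. The fall-rise class held Car4, a carbonic anhydrase of vessels and epithelia, with 49.3 ± 6.99, 1.58 ± 0.426 and 74.9 ± 9.48 CPM. Myrf, the transcription factor that drives myelin genes, had 27.1 ± 0.708, 2.29 ± 0.621 and 35.8 ± 14.7 CPM. The membrane protein gene Tmem125, the kinase gene Cdk18 and the actin-capping gene Tmod1 fell and rose as well.

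In the pairs of paralogs or partners fixed beforehand, the ratio changed across the stages for 20 of 20 pairs (exact permutation test, highest adjusted p = 0.018). Since 16441 of 17971 genes differed across the stages, ratios of other genes may change as often. No unrelated pairs were tested, so the count does not set these pairs apart. The ratio shifted toward the first gene, taken as the adult or neuronal member, from E9.5 to P60 in 18 pairs, 11 of them in both steps. In 15 pairs the mean log2 ratio turned from negative to positive. CPM were not scaled to transcript length, so a log2 ratio of 0 need not mean equal abundance. The change of sign therefore does not show that the first gene overtook the second. For Scn1a/Scn3a the E9.5 mean was within its spread of a log2 ratio of 0 (-0.11, SD 0.35). A gain in ratio need not be a rise of the first gene. Dnmt3a itself fell from 164 CPM at E9.5 to 17.6 CPM at P60, and Smarcc2 from 606 CPM at E14.5 to 163 CPM at P60. The libraries are of whole tissue, so for these ratios a switch within cells and a change in the mix of cells cannot be told apart. The BAF subunit pair Actl6b/Actl6a went from a log2 ratio of -6.89 ± 0.07 (SD) to 1.05 ± 0.05 and 2.25 ± 0.17, and Smarcc2/Smarcc1 from -1.81 ± 0.05 to 1.01 ± 0.05 and 2.12 ± 0.03. Dpf1/Phf10 gained 4.02 in the first step and then moved by -1.47, or by -0.90 with the length and GC trend removed across all libraries. Ss18l1/Ss18 and Dpf3/Dpf2 likewise gained first, by 4.04 and 3.67, and then moved by -0.38 and -0.87. The second step of Ss18l1/Ss18 was -0.17 with that trend removed, and that of Dpf3/Dpf2 was -0.38 with a pseudocount of 5 CPM. The catalytic pair Smarca2/Smarca4 gained in both steps, from -3.91 ± 0.25 to -1.86 ± 0.62 and 0.80 ± 0.28. Ezh1/Ezh2, the alternative Polycomb enzymes, moved mainly in the second step (6.35), as did Tubb4a/Tubb2b (5.40) among tubulins. Ptbp2/Ptbp1, the splicing repressors of neurons and progenitors, gained 3.02 and 1.77. Among metabolic isoforms, Eno2/Eno1 gained 5.68 and 3.48, and Ldhb/Ldha 4.77 and 1.57.

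Some receptor, kinase and channel pairs dipped at E14.5. Scn1a/Scn3a, the adult over the embryonic sodium channel, moved by -2.78 and then gained 5.74. Grin2a/Grin2b, NMDA receptor subunits, moved by -5.75 and 5.40, and by -5.28 and 4.88 with the length and GC trend removed across all libraries. Camk2a/Camk2b, the synaptic kinase subunits, moved by -3.12 and 2.65. At E9.5 Grin2a and Grin2b had 1.11 and 0.277 CPM and Scn1a and Scn3a 1.16 and 1.29 CPM, near or below the pseudocount of 1 CPM. For Grin2a/Grin2b the size of the first step depended on it, at -7.33 with 0.1 CPM and -4.24 with 5 CPM. For Scn1a/Scn3a the first step moved less, to -2.77 and -2.49. The fall of Grin2b itself from E14.5 to P60 (-1.82) became 0.02 with the trend removed. The net changes of Grin2a/Grin2b and Camk2a/Camk2b, -0.35 and -0.47, turned to 0.13 and 0.03 with a pseudocount of 5 CPM, so no net direction is given. Slc12a5/Slc12a2, the chloride exporter over the importer, gained 3.62 and 1.04, and Dlg4/Dlg3, postsynaptic scaffolds, gained 2.28 and 0.20. Dnmt3a/Dnmt3b, the methyltransferases, gained 4.01 and then moved by -1.31, a second step that was -0.08 with the trend removed, 0.05 with a pseudocount of 0.1 CPM and -2.35 with 5 CPM, so no direction is given for it. Bcan/Vcan, matrix proteoglycans, gained 5.27 and 6.21, and Hbb-bs/Hbb-y, adult over embryonic globin, 9.26 and 4.09. The second step of the globins was 6.22 with 0.1 CPM and 2.11 with 5 CPM, since Hbb-y had 0.167 CPM at P60. The first steps of Actl6b/Actl6a (9.33 and 6.04) and Bcan/Vcan (6.51 and 3.56) also depended on the pseudocount. Reads of Hbb-bs may be shared with the near-identical Hbb-bt.

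**Figure D3:**
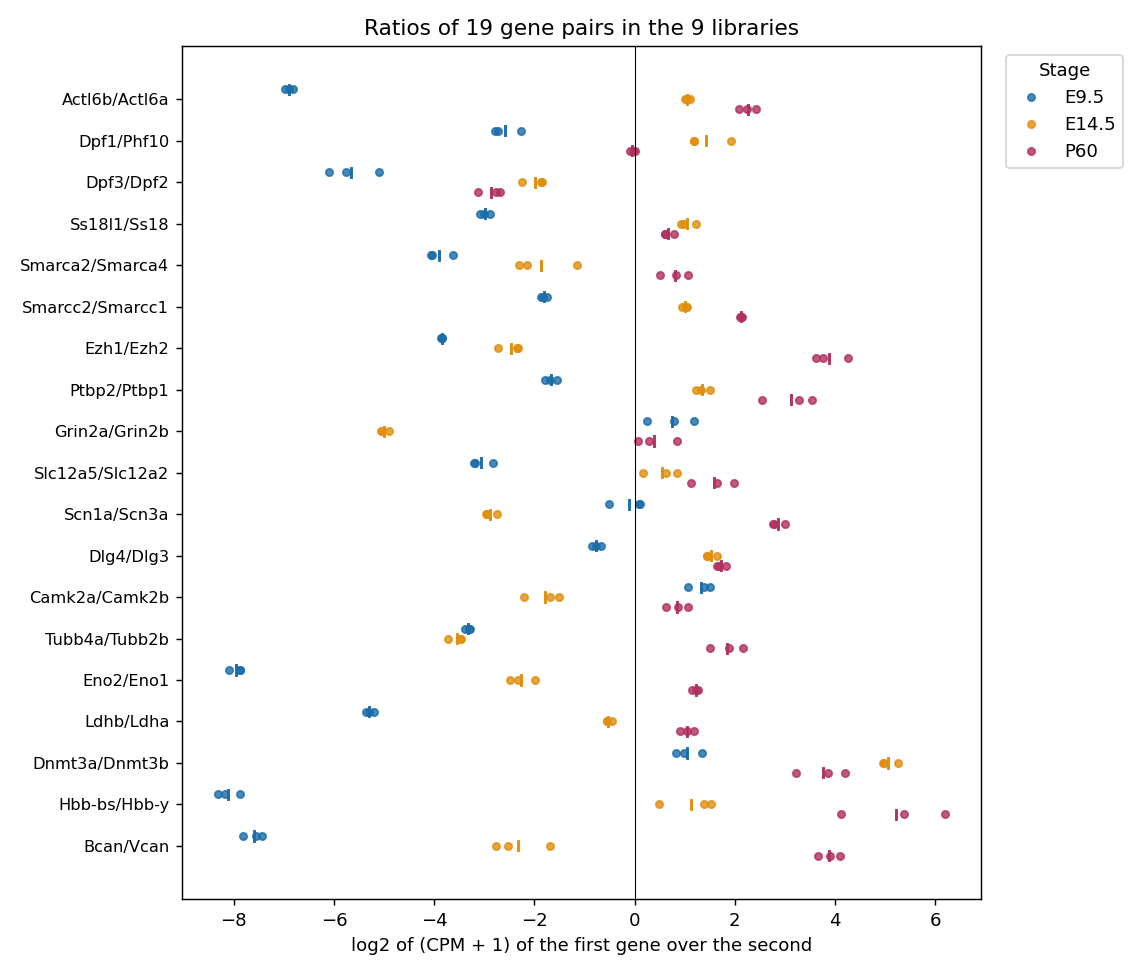
Log2 of (CPM + 1) of the first gene over the second for 19 of the 20 gene pairs, with a point per library and a bar at the mean of each stage. The ratio Actl6b/Actl6a is below -6 in every E9.5 library and above 0 in every later one.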

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

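The alternatives were fixed before the data were examined, except removal of the length and GC trend (within stages or across all libraries) and the fit without the first library of both embryonic stages, which were chosen after seeing the data. Over all settings, named genes kept direction and side of the threshold in 10576 results, lost the call in 184, gained it in 23 and reversed in 4. With the trend removed across all libraries, Smarca4 was at -0.37 for E14.5 against E9.5, Grin2b at 0.02 and Smarca2 at 0.75 for P60 against E14.5, and Smarcc2 at 0.33 for P60 against E9.5. Of these, only Grin2b had been called with the opposite sign in the main setting. With a pseudocount of 5 CPM the net change of Grin2a/Grin2b was 0.13 and that of Camk2a/Camk2b 0.03. The pseudocount acts most where a gene has few reads in a stage, at E9.5 or P60. With the trend removed, 20 of 20 pair ratios still changed.

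A test against 2-fold left 5564 genes for E14.5 against E9.5 and 7932 for P60 against E14.5, by its stricter construction. With no minimum size the classes rise-rise, fall-fall, rise-fall and fall-rise held 2664, 2618, 2075 and 1544 genes, and with 4-fold in both steps 669, 312, 354 and 206. With the correlation estimated per list, 0 lists were called in each contrast, and the lowest adjusted p was 0.079. The unadjusted p was under 0.05 for 8, 11 and 11 lists. Over all settings 21 list calls were gained and 83 lost, of which 70 were lost to the estimated correlation.

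Leaving out each library in turn gave 10516 to 12360, 12923 to 14139 and 14400 to 15549 changed genes in the 3 contrasts. At least 2-fold changes ranged over 7680 to 8103, 9947 to 10653 and 12175 to 12499, and those across the 3 stages over 16186 to 17056. The classes ranged over 1603 to 1700, 1200 to 1304, 1131 to 1315 and 599 to 763, and called lists over 18 to 20, 25 to 26 and 26 to 29. Named genes kept direction and side of the threshold in 3831 leave-one-out results, lost the call in 61 and gained it in 5.

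With the replicate number as a block, 12121, 14015 and 15081 genes changed in the contrasts and 16699 across the stages, with 18, 25 and 27 lists called. The block moved no count by more than 1.5 times. Deviations of same-numbered libraries correlated across genes at 0.37, 0.10 and 0.17 for replicate 1, 0.14, 0.11 and 0.34 for replicate 2, and 0.21, -0.10 and -0.22 for replicate 3. Not every library correlated best with its own number, so the numbers are not taken to pair the samples.

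Upper quartile scaling moved the median log2 fold change of all genes to 0.10 for P60 against E14.5 and 0.20 for P60 against E9.5, and library totals moved it to -0.20 for P60 against E14.5, from -0.06, 0.05 and -0.06. Changes of that size, and the balance of higher and lower among all changed genes, are not separable from scaling. The medians of 5 lists near 0 crossed it under another scaling, none of them called. With the trend removed, 13028, 14164 and 15411 genes changed (across all libraries) or 12888, 14473 and 15417 (within stages), and without the first library of both embryonic stages 11284, 14242 and 15224. Thinning all libraries to the smallest total left all 433 named results on the same side of the threshold, but the totals were too alike for this to show what depth limits. Counting error is widest for genes with 1 to 3 reads in a stage, such as Igf2bp1, whose ratio between E9.5 and P60 had an interval of 12500 to 2750000.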

Other observations

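The gene families and library differences given here were picked after the values were seen, from 104 families of at least 15 tested genes sharing a symbol stem. The tests of a muscle source and of sex were also chosen after their results were seen, and those of length and quality before. The clustered protocadherins, cell surface proteins that give neurons their identity, rose from E9.5 to E14.5. All 21 tested Pcdhb genes were higher (median 5.95), under every scaling, and 19 of 21 Pcdhg genes were higher (18 or 19 across scalings). From E14.5 to P60 the Pcdhb genes showed no common direction, with 5 higher and 3 lower and a median that changed sign with the scaling (-0.11 to 0.18), while 15 of 21 Pcdhg genes fell (camera adjusted p = 0.033, but 0.93 with an estimated correlation and 0.14 with the length and GC trend removed). Members of each cluster are close in sequence, so reads may be shared between them. Nucleoporin genes (Nup, nuclear pore) fell in 19 of 20 cases in each step, with 16 to 19 across scalings in the second. Hnrnp genes, which package pre-mRNA, fell in 15 and then 19 of 20 cases, and 40 of 53 translation initiation genes (Eif) fell in the first step. Collagen genes (Col) fell in 32 of 44 and zinc finger genes (Zfp) in 211 of 370 cases from E14.5 to P60. Camera called 29 and 34 families in the 2 steps, and 0 with an estimated correlation.

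Single genes differed between the P60 libraries, with no common order of the libraries. The dopamine transporter gene Slc6a3 had 95.2, 15.6 and 31.3 CPM in the 3 libraries, and Th, of dopamine synthesis, 42, 11.7 and 12.4 CPM. Avp, the vasopressin gene, had 18.7, 4.67 and 167 CPM and Hcrt 28.4, 74.5 and 83.9 CPM. The choroid plexus genes Prlr and Kl were highest in the second library (23.6 and 38 CPM), while Ttr was highest in the third (4560 CPM against 1940 and 3640). No explanation was tested.

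Long transcripts were lower and short ones higher at P60 than at E14.5. A length bias acting on all genes alike would appear also among genes of a single function, and within the fixed lists the slope was -0.72 per doubling of transcript length (95% interval -0.90 to -0.55, 692 genes), against -0.37 over all genes. The slope was negative in 18 of 19 lists, so a length bias may contribute. A bias of the same size per doubling for every gene would give the slope of all genes within lists as well. The interval lies wholly below that value. Medians over all genes did not fall evenly with length, however. They were 0.57 under 1 kb, 0.57 at 1 to 2 kb and -1.32 over 8 kb. The comparison of slopes therefore cannot tell whether a bias alike for all genes accounts for the list slope. A shared quality difference that also separates libraries of a stage was not decided, as the correlation across genes with the step was 0.07 and 0.16 within E14.5 and P60. Length trends also separated libraries of a stage. Against the other libraries of its stage, each library had a slope of -0.24, 0.13 and 0.11 at E14.5 and -0.06, 0.25 and -0.19 at P60. A stage difference tied to length would give the same slopes within lists, and no separate measure of RNA quality was used, so a biological shift toward short transcripts remains open.

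The first E9.5 library held heart muscle transcripts. This pattern was first written for muscle and epithelial genes together, and was narrowed to muscle after 1 of 11 epithelial genes proved more than 2-fold above both other E9.5 libraries (median log2 excess 0.42). All 7 tested muscle genes were that far above (median 5.12), and Myh6, the atrial myosin, had 70.1 CPM against 0.365 and 0.383 CPM. Heart tissue left with the head may be the source, though no anatomical record tests this, and P60 libraries also express Myl4, Tnnt2 and Tnni1. A length bias was excluded, since the excess was 5.25 with the trend removed.

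Each E9.5 library held both Xist, the transcript of the inactive X chromosome, at 326, 982 and 762 CPM, and Y-linked transcripts at 100, 53.5 and 95.1 CPM. The CPM of these sex-linked transcripts are scaled to library totals alone. The first and second E14.5 libraries had Y-linked reads (171 and 189 CPM) with Xist at 0.307 and 0.445 CPM, and the remaining one had Xist at 1120 CPM with 0.0311 CPM of Y-linked reads. P60 libraries had Xist at 21.7, 36.1 and 20.3 CPM and Y-linked reads at 0.128, 0.113 and 0 CPM. They thus carried the Xist signal alone, at lower levels than the E14.5 library with Xist. The sex signals differed between the stages and sex was not in the fit, so the contrasts do not separate sex from stage. Each E9.5 sample may be a pool of embryos of both sexes, as each signal was at least 419 times its level in libraries with the other signal alone. Reads assigned to the wrong library do not account for it at the rates seen elsewhere. Xist in the E14.5 libraries with Y-linked reads was 0.137% of the lowest E9.5 value, and Y-linked reads in libraries with Xist alone were at most 0.239% of the lowest Y-linked value at E9.5.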
